A study of Arabidopsis thaliana with 12 samples.

How the data were processed

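Whole seedlings of Col-0 and Kn-0 gave 12 libraries of polyadenylated RNA, 6 per accession, grouped by accession and treatment as the labels state. The submitters' processing notes name STAR, featureCounts, DESeq2 and TAIR10 without versions or roles. Per the file headers, the deposited gene tables hold the authors' mean signal (counts after size-factor normalization, averaged over the libraries of an accession). The deposited log2 fold changes and their standard errors are from the authors' fit of ABA against mock, unshrunken, as checked by their ratio to the statistic. The deposited Wald statistic of the authors' fit is a score, and so is the deposited inclusion difference, mock minus ABA, of the splicing tables. The deposited p-value and adjusted p-value columns are those of the authors' DESeq2 and rMATS tests. The header of the deposited Kn-0 gene table is shifted by 1 column, which was allowed for. Deposited splicing tables were made by the authors with rMATS (named in the file names, version not given) from junction reads, in 4 event types.

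Direction was checked against the junction reads of the genes, whose log2 ratio of ABA over mock had r = 0.974 with the deposited fold change across 13299 genes in Col-0 and r = 0.971 across 13298 in Kn-0. The accession tables were normalized separately and each holds 5032 genes that the other lacks, with 27801 in both, so gene levels were not compared between accessions. Of the identifiers, 99.1% and 98.6% were in the TAIR10 reference. In the splicing tables the commas between the counts of 3 libraries were often lost, and the counts of 59.63% of Col-0 and 62.45% of Kn-0 events were recovered by dividing the digits so that the deposited inclusion levels were met within 0.0005. This failed for 94 and 123 events, which were left out, and was ambiguous for 0. Pairs of replicates differed by a chi-square per degree of freedom of 3.23 to 10.16, so none were duplicates.

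Genes were called at the authors' adjusted p under 0.05. The difference between accessions was tested by the Wald z of the difference between the deposited fold changes, two-sided, with Benjamini-Hochberg adjustment over 22001 genes. In the test on simulated data 44.8%, 76.1% and 89.4% of differences of 0.5, 1 and 2 on the log2 scale were recovered, and 2.8% of calls were false. Of the gene lists, 21 were written before the data were examined, as were the tests, thresholds, named-gene rule and most alternatives. The lists of iron deficiency genes and of indole glucosinolate and camalexin genes were added after the data were seen. Lists were tested per direction by Fisher's exact test against all other tested genes, adjusted over lists and directions, and their differences were set against 10000 random lists. These were first matched on mean expression, but the Kn-0 response had a slope of 0.907 on that of Col-0, so a strongly changed list would differ by that alone. The slope was fitted over genes changed in either accession whose responses did not differ. The random lists were then matched on the Col-0 change, each member being replaced by 1 of the 100 nearest genes, without mean expression. This used the Col-0 estimate without its error, so genes with a change too large by chance can enter. Percentiles are those of this second match unless stated.

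Splicing events were called at the authors' rMATS FDR under 0.05 with an inclusion difference of at least 0.1 and a mean of at least 10 junction reads per library. Because rMATS could not be rerun, a refit compared pooled logits of inclusion and skipping reads, with 0.5 added, a Pearson dispersion moderated with limma 3.58.1 in R 4.3.3 and never under 1, and a moderated Wald statistic. It used events with at least 10 junction reads in every library and a mean inclusion level from 0.02 to 0.98, adjusted within event type. The moderation had infinite prior degrees of freedom in both accessions, so every event received the same dispersion, 1.55 in Col-0 and 1.5 in Kn-0, and its own replicate spread did not enter its p. An alternative chosen after this was seen used the larger of the common and the event's own dispersion. The mean dispersion of the data rose with depth, from 1.32 at up to 20 reads to 2.07 in the deepest events in Col-0 and from 1.27 to 2.03 in Kn-0. A first simulation, with a beta-binomial correlation of 0.01 and a median dispersion of 1.97 in Col-0 and 2.06 in Kn-0, recovered 7.6% and 9.1% of changes of 0.3. A second simulation was then made with the constant dispersion of the refit, and it recovered 7.5%, 34.3% and 62.1% of changes of 0.1, 0.2 and 0.3 in Col-0 and 10.4%, 40.3% and 75.8% in Kn-0, with 1.4% and 1.2% of calls false. The refit is therefore weak for small changes. The second simulation gave every event the dispersion that the refit assumes. Its share of false calls therefore does not cover events with a larger spread of their own. Among the called events of the data, the own dispersion reached 9.15 in Col-0 and 5.57 in Kn-0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

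Events were to be paired between accessions by identical coordinates, but 0 events had them, and 5.04% of Kn-0 events lay inside their gene's TAIR10 position against 100.0% of Col-0 events. They were paired instead by type, gene, strand and the spacing of all 6 exon boundaries, which matched 55204 events. A match on splice junctions only, which gave 89497, was added after the first was seen to pair 55 of the 222 called Col-0 events. TAIR10 positions are given for Kn-0 events only through a matched Col-0 event.

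Named genes were, per accession, the 6 largest increases and 6 largest decreases with a symbol in the reference and a mean of at least 50 normalized counts, and up to 3 members per list with the smallest adjusted p. For the difference between accessions they were the 8 largest positive and 8 largest negative differences with that mean in either table. Named events were the 4 largest retained introns and 2 of each other type per accession with at least 20 junction reads in every library, every called event in the lists of splicing factors and core ABA signalling, and the 5 largest mock differences. Events called in both accessions and the other list members named beside a difference were chosen after their values were seen, as was the minimum of 80 reads for the plotted events. The libraries of a group were told apart by their place in the cells of the splicing tables, an order assumed to be constant across events and not stated to be that of the replicate numbers. Alternatives changed thresholds, minimum effects, read minimums, centring, moderation, the test and the left-out library of the refit. Gene-level results could not be refitted without single libraries, because the gene tables hold 1 value per accession.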

Results

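Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings of the natural accessions Col-0, the reference strain, and Kn-0. Seedlings aged 4 days were moved for 3 h to control medium (mock) or to medium with 5 µM abscisic acid (ABA), the hormone that plants accumulate under drought and in maturing seeds. There were 12 libraries in 4 groups, with 3 biological replicates in each. Gene-level values came as 1 table of fold changes per accession, and splicing events came with junction reads for each library. Counted over 1 event per gene, junction reads per library ran from 14251767 to 15550074 in Col-0 and from 14595973 to 15282968 in Kn-0. The crossed design asks how ABA changes expression and splicing in each accession, and whether the accessions differ in that response.

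In Col-0, ABA raised the phosphatases that hold its own signalling off and the proteins of desiccation tolerance, and lowered several of its receptors. All 9 clade A protein phosphatases 2C rose (adjusted p = 6.6e-06 for the list, Fisher's exact test), as did 9 when adjusted over the list alone. In the authors' deposited table, the log2 fold change of ABA over mock was 7.42 ± 0.218 (standard error) for HAI3 (AT2G29380), 6.34 ± 0.13 for HAI1 (AT5G59220) and 3.32 ± 0.079 for PP2CA (AT3G11410). All 18 dehydrins and late embryogenesis abundant (LEA) proteins rose (adjusted p = 9.3e-12), as did 18 when adjusted over the list alone. The authors' deposited table gave LEA7 (AT1G52690) a log2 fold change of 7.08 ± 0.243, KIN1 (AT5G15960) 5.24 ± 0.128 and LTI30 (AT3G50970) 4.78 ± 0.119. Of 29 ABA-related transcription factors, 24 rose, 0 fell and 5 did not pass (adjusted p = 1.2e-11), against 25 higher when adjusted over the list alone. ATHB7 (AT2G46680) and ABF3 (AT4G34000) had log2 fold changes of 4.05 ± 0.114 and 2.45 ± 0.059 in the authors' deposited table.

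Genes of ABA turnover, compatible solutes and water transport also rose in Col-0. Among genes of ABA synthesis, breakdown and transport, 10 of 16 measured members rose and 1 fell (adjusted p = 0.0016 for higher), with 11 changed when adjusted over the list alone. The ABA hydroxylases CYP707A1 and CYP707A2 and the synthesis enzyme NCED3 had log2 fold changes of 3.55 ± 0.126, 2.85 ± 0.169 and 2.57 ± 0.123 in the authors' deposited table. Of 9 genes of proline and raffinose sugar metabolism, 6 rose and 1 fell (adjusted p = 0.012 for higher), with 7 changed when adjusted over the list alone. GOLS2, an enzyme of galactinol synthesis, stood at 7.05 ± 0.239 in the authors' deposited table. Of 17 aquaporins, which carry water across membranes, 10 rose and 2 fell (adjusted p = 0.0028 for higher), with 13 changed when adjusted over the list alone, but 0 rose by a log2 change of at least 1 (adjusted p = 1). The authors' deposited table gave PIP2;1 a log2 fold change of 0.92 ± 0.053 and PIP2;6 0.81 ± 0.058. All 7 heat shock genes rose (adjusted p = 0.00013), as did 7 when adjusted over the list alone, with HSP17.6A at 2.81 ± 0.312 in the authors' deposited table.

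Receptors, wall-loosening genes and root markers fell more often in Col-0. Of 12 measured PYR/PYL receptors, 7 fell and 3 rose (adjusted p = 0.011 for lower), with 10 changed when adjusted over the list alone. The authors' deposited table gave PYL6 (AT2G40330) a log2 fold change of -5.72 ± 0.289, PYL4 -3.45 ± 0.087 and PYL5 -2.49 ± 0.155. Of 20 expansins and xyloglucan enzymes, which loosen the growing wall, 12 fell and 4 rose (adjusted p = 0.00037 for lower), with 18 changed when adjusted over the list alone. EXPA1 was at -2.4 ± 0.08, XTH20 at -2.29 ± 0.219 and XTH19 at 1.15 ± 0.104 in the authors' deposited table. Of 9 root cell markers, 6 fell and 1 rose (adjusted p = 0.01 for lower), with 8 changed when adjusted over the list alone, but 1 fell by a log2 change of at least 1 (adjusted p = 0.85). PLT1, a regulator of the root stem cell niche, was at -1.2 ± 0.175 and CASP5, a protein of the endodermal barrier, at 0.9 ± 0.147 in the authors' deposited table. The largest changes among genes with a reference symbol and a mean of at least 50 normalized counts also included ATHSP22.0 at 8.13 ± 0.678, CSLG2 at 7.58 ± 0.868 and APX2 at 6.95 ± 0.882 in the authors' deposited table. On the lower side, the authors' deposited table gave GLIP2 a log2 fold change of -5.58 ± 0.44, CYP71A12 -4.99 ± 0.63, IMS2 -4.64 ± 0.185, the iron transporter IRT1 -4.55 ± 0.098 and CP1 -4.33 ± 0.093.

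Of 23687 genes tested in Col-0, 9068 passed an adjusted p of 0.05 in the authors' deposited table, 4700 higher and 4368 lower. With a log2 change of at least 1 the counts in the authors' deposited table were 1273 and 933. Members of a list are not independent of each other, so the p-values of lists are too small.

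In Kn-0, the phosphatases and the desiccation proteins rose as whole lists too. All 9 clade A phosphatases rose (adjusted p = 2.5e-05), with 9 when adjusted over the list alone, and all 18 dehydrins and LEA proteins rose (adjusted p = 6.4e-11), with 18 when adjusted over the list alone. Of 29 ABA-related transcription factors, 26 rose and 0 fell (adjusted p = 1.7e-12), with 26 when adjusted over the list alone. The authors' deposited table gave log2 fold changes of 6.96 ± 0.071 for RD29B (AT5G52300), 6.89 ± 0.258 for the lipid transfer protein LTP4 (AT5G59310), 6.64 ± 0.098 for TSPO (AT2G47770) and 6.61 ± 0.086 for KIN1. LEA7 and HAI3 stood at 6.56 ± 0.198 and 6.4 ± 0.17 in the authors' deposited table. Among genes with a reference symbol and a mean of at least 50 normalized counts, the largest decreases in the authors' deposited table were GLIP2 at -5.44 ± 0.431, PYL6 at -4.33 ± 0.211, CP1 at -3.81 ± 0.24, IRT1 at -3.4 ± 0.247, CRK30 at -3.31 ± 0.251 and MYB10 at -3.22 ± 0.274.

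Genes of ABA synthesis, breakdown and transport rose in 11 of 17 measured members and fell in 1 in Kn-0 (adjusted p = 0.0023 for higher), with 12 changed when adjusted over the list alone. Aquaporins rose in 10 of 17 members and fell in 2 (adjusted p = 0.0092 for higher), with 13 changed when adjusted over the list alone, but 0 rose by a log2 change of at least 1 (adjusted p = 1). Of 21 light-harvesting and Rubisco small subunit genes, 14 rose by small amounts and 1 fell (adjusted p = 0.00025 for higher), with 17 changed when adjusted over the list alone, but 0 rose by a log2 change of at least 1 (adjusted p = 1). The authors' deposited table gave LHCB2.3 a log2 fold change of 0.3 ± 0.071, LHCB2.2 0.25 ± 0.068 and RBCS1B -0.42 ± 0.066. In Col-0, 5 of 20 of these genes rose and 1 fell (adjusted p = 0.95 for higher), with 6 changed when adjusted over the list alone. No member passed the test of a difference between accessions, and the median difference was 0.01 on the log2 scale. Expansins and xyloglucan enzymes fell in 11 of 20 members and rose in 6 (adjusted p = 0.0074 for lower), with 18 changed when adjusted over the list alone, but 2 fell by a log2 change of at least 1 (adjusted p = 0.41). Heat shock genes rose in 5 of 7 members (adjusted p = 0.046), with 5 when adjusted over the list alone.

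Some lists that passed in Col-0 did not pass in Kn-0, without a test of that contrast between the lists. Of 13 receptors, 6 fell and 3 rose in Kn-0 (adjusted p = 0.16 for lower), with 9 changed when adjusted over the list alone, although the 4 that fell by a log2 change of at least 1 passed as a list (adjusted p = 0.0019). Root cell markers fell in 5 of 9 members and rose in 1 (adjusted p = 0.12 for lower), with 6 changed when adjusted over the list alone. Genes of proline and raffinose sugar metabolism rose in 5 of 9 members and fell in 3 (adjusted p = 0.15 for higher), with 9 changed when adjusted over the list alone. P5CS1, an enzyme of proline synthesis, was at 2.79 ± 0.065 and DIN10 at -0.93 ± 0.055 in the authors' deposited table. Of 23710 genes tested in Kn-0, 10528 passed in the authors' deposited table, 5439 higher and 5089 lower. With a log2 change of at least 1 the authors' deposited table held 1163 and 592.

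Splicing factors changed in few members. Of 20 SR splicing factors, 2 rose and 0 fell in Col-0 (adjusted p = 1 in each direction), with 1 when adjusted over the list alone, and 1 rose and 3 fell in Kn-0 (adjusted p = 1 in each direction), with 4 when adjusted over the list alone. SR30 was at 0.51 ± 0.067 in Col-0 and 0.46 ± 0.054 in Kn-0 in the authors' deposited table of each accession. Of 15 other splicing and RNA-binding proteins, 2 rose and 2 fell in Col-0 (adjusted p = 1 in each direction), with 4 when adjusted over the list alone, and 0 rose and 5 fell in Kn-0 (adjusted p = 0.57 for lower), with 5 when adjusted over the list alone. The glycine-rich RNA-binding protein GRP8 was at -0.87 ± 0.095 in Col-0 and -0.73 ± 0.061 in Kn-0 in the authors' deposited table of each accession. SnRK2 kinases, some of which ABA signalling activates, rose in 5 of 10 members and fell in 2 in both accessions (adjusted p = 0.11 in Col-0 and adjusted p = 0.18 in Kn-0 for higher), with 7 changed in each when adjusted over the list alone. SNRK2.6, the kinase of guard cells, was at 1.12 ± 0.07 in Col-0 and 0.78 ± 0.065 in Kn-0 in the authors' deposited table of each accession.

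The ABA responses of the accessions went together across genes. Over 22001 genes tested in both tables, which are not independent replicates, the fold changes had a Pearson r of 0.845 and a Spearman rho of 0.795. Genes that rose in both numbered 3931, against 1113.6 expected from independent lists (odds ratio 66.8, 95% confidence interval 60.6 to 73.7). Genes that fell in both numbered 3394, against 968.1 expected (odds ratio 39.1, 95% confidence interval 35.7 to 42.8). Of 7366 genes called in both accessions, 7325 changed in the same direction and 41 in opposite directions, and the change was smaller in Kn-0 for 62.2%.

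**Figure D1:**
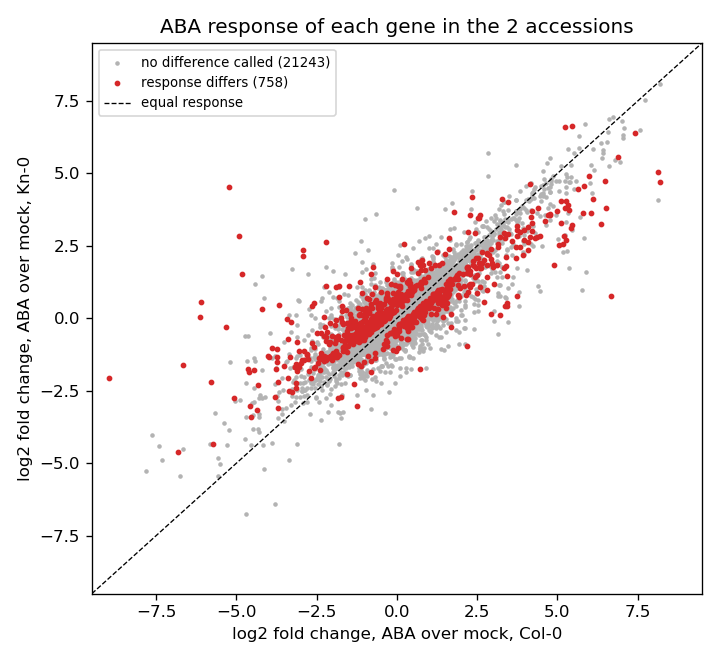
Log2 fold change of ABA over mock in Col-0 (x axis) and Kn-0 (y axis), with 1 point per gene tested in both deposited tables. Red points are the 758 genes whose response differed between the accessions, and the dashed line marks an equal response.

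The response to ABA differed between the accessions at 758 genes, 428 with a more positive and 330 with a more negative change in Kn-0 (Wald test of the difference of the deposited fold changes, Benjamini-Hochberg adjusted). Of these, 283 had risen in Col-0 and rose less, did not rise or fell in Kn-0. Another 321 had fallen in Col-0 and fell less, did not fall or rose in Kn-0. Clade A phosphatases had a median difference, Kn-0 minus Col-0, of -0.39 on the log2 scale, and 4 of 9 passed. This was at percentile 71.7 of 10000 random lists matched on the Col-0 change, whose median was -0.6, and 0 passed once the Kn-0 changes were divided by the slope of Kn-0 on Col-0 (0.907). HAI3 differed by -1.02 ± 0.28 (standard error, adjusted p = 0.01) and PP2CA by -0.39 ± 0.1 (adjusted p = 0.0039). Dehydrins and LEA proteins had a median difference of -0.26, at percentile 95.7 of lists matched in this way, whose median was -0.69. Of 18 members 7 passed, or 6 after division by the slope. After that division the median difference of the list was 0.16, so the 6 cannot be read as genes that rose less in Kn-0. Within that list ERD10 differed by -0.69 ± 0.13 (adjusted p = 2.6e-05), whereas KIN1 rose by more in Kn-0, by 1.37 ± 0.15 (adjusted p = 5.8e-16). Heat shock genes had a median difference of -0.85, at percentile 1.3 of matched lists, and 3 of 7 passed, or 1 after division by the slope. Matched on mean expression instead, the phosphatases, the dehydrins and LEA proteins, and the heat shock genes were each at percentile 0.0. Neither match held both expression and the Col-0 change, so the percentiles do not settle whether a list differs. The matching on the Col-0 change and the slope were chosen after the data were seen, and the percentiles are not adjusted over the lists. Other lists also stood under most of their matched lists, with 0 members that passed: other splicing and RNA-binding proteins (median difference -0.1, percentile 0.6), cell cycle genes (-0.11, percentile 1.1) and seed storage and oil body genes (-0.49, percentile 1.9). NCED3 differed by -0.67 ± 0.15 (adjusted p = 0.0011), PYL6 by 1.4 ± 0.36 (adjusted p = 0.0051) and TSPO by 1.19 ± 0.16 (adjusted p = 3.1e-11). After division by the slope ERD10 (adjusted p = 0.13), NCED3 (adjusted p = 0.085) and PYL6 (adjusted p = 0.2) did not pass, whereas KIN1 and TSPO did (adjusted p = 2.7e-34 and adjusted p = 2.1e-26).

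Among the 758 genes that passed, with a mean of at least 50 normalized counts in either table, the largest negative differences were those of AT4G17580 (-5.88 ± 1.34, adjusted p = 0.00093), AT5G05220 (-3.5 ± 0.72, adjusted p = 0.00014), GASA3 (-3.12 ± 0.53, adjusted p = 1e-06), CYP76C2 (-3.1 ± 0.88, adjusted p = 0.016) and the small heat shock protein ATHSP22.0 (-3.07 ± 0.72, adjusted p = 0.0015). BPS3, AT4G10500 and OCT1 followed at -3.01 ± 0.35, -2.98 ± 0.33 and -2.92 ± 0.26. By the same rule, the largest positive differences were those of AT1G26420 (5.1 ± 1.25, adjusted p = 0.0028), AT2G13900 (5.01 ± 1.53, adjusted p = 0.035), NAC042 (4.49 ± 1.3, adjusted p = 0.02), CYP81F2 (4.15 ± 1.04, adjusted p = 0.0038) and AT5G59680 (3.59 ± 0.55, adjusted p = 2.6e-08). UMAMIT36, PER4 and AT3G28580 followed at 3.43 ± 0.47, 3.16 ± 0.66 and 3.1 ± 0.68. Some of these genes had a low mean in 1 of the tables, which need not reflect a low level in that accession: in the authors' deposited table the mean of normalized counts was 9.0 for AT4G17580, 3.8 for AT2G13900 and 17.0 for AT3G28580 in Col-0, and 6.3 for CYP76C2, 37.8 for AT1G26420 and 39.1 for UMAMIT36 in Kn-0. These would be left out by a minimum of 50 in both tables. Of the genes with positive differences, only NAC042, CYP81F2 and PER4 had an event with a mean of at least 10 junction reads in Kn-0. In each, 1 Kn-0 ABA library stood apart, with junction reads of 47, 7 and 3 over the replicates for NAC042, 74, 6 and 4 for CYP81F2, and 125, 36 and 47 for PER4. The other positive ones could not be checked, and AT1G26420 had a standard error of 1.204 in Kn-0 against 0.342 in Col-0. Of the negative ones, AT4G17580 had 293, 277 and 269 reads and AT4G10500 had 20, 16 and 20. Without its first ABA library, the Kn-0 log2 ratio of junction reads moved from 0.29 to -1.51 for NAC042, from 0.24 to -2.12 for CYP81F2 and from -0.36 to -1.09 for PER4.

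Splicing changed under ABA at few events, most of them retained introns. In Col-0, the authors' rMATS test with an inclusion difference of at least 0.1 called 222 of 161119 events, in 176 genes, of which 105 had higher and 117 lower inclusion under ABA. They were 137 retained introns, 29 skipped exons, 18 alternative 5' splice sites and 38 alternative 3' splice sites. In Kn-0, 161 of 166364 events were called, in 134 genes, with 81 higher and 80 lower. Retained introns, taken once per gene, were higher in 55 genes and lower in 68 in Col-0 (two-sided exact binomial p = 0.28), and higher in 38 and lower in 53 in Kn-0 (two-sided exact binomial p = 0.14). Among events with a mean of at least 20 junction reads the share of genes with higher retention was 50.6% in Col-0 and 51.1% in Kn-0. Among the calls of the refit described below it was 68.2% (two-sided exact binomial p = 0.13) and 73.3% (two-sided exact binomial p = 0.12).

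Retention of an intron of CEL5, a cellulase gene (AT1G22880), rose in both accessions. This 81-base intron of the coding region (TAIR10 chromosome 1, 8095965 to 8096045) had an inclusion level of 33.7% ± 2.2 (SD, n = 3) in mock and 77.1% ± 10.3 under ABA in Col-0. The refit with limma-moderated dispersion, common to all events, gave adjusted p = 2.9e-21, or adjusted p = 3.4e-07 with the event's own dispersion. In Kn-0 it went from 30.9% ± 0.8 to 79.8% ± 5.8 (adjusted p = 9.5e-27). An intron in the 5' UTR of ERD15 (AT2G41430, chromosome 2, 17269491 to 17269719) rose in Col-0 from 62.8% ± 1.4 to 92.9% ± 3.8 (adjusted p = 3.7e-11), and in Kn-0 from 76.5% to 91.5% (rMATS FDR 1.1e-07). A 5' UTR intron of the kinase gene SNRK2.10 (chromosome 1, 22441935 to 22442107) rose in Col-0 from 62.0% ± 3.4 to 72.4% ± 2.8 (adjusted p = 6.4e-06, or adjusted p = 0.035 with its own dispersion). It had at least 816 junction reads per library and no matched Kn-0 event. An 850-base segment at an alternative 5' splice site of KAT5 (chromosome 5, 19816923 to 19817772) rose in Col-0 from 33.1% ± 1.7 to 51.2% ± 1.8 (adjusted p = 1.2e-08).

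In Kn-0, retention rose in GPDHC1 (AT2G41540) from 26.3% ± 1.5 (SD, n = 3) to 63.7% ± 2.0 and in AT2G25350 from 10.9% ± 1.1 to 38.0% ± 3.8 (adjusted p = 2.5e-13 for each). The GPDHC1 level sets retention against 1 spliced form only. Against a spliced form with a nearby splice site, retention over nearly the same intron went from 4.5% to 17.3% (adjusted p = 3e-25 in the refit). The AT2G25350 intron was called in Col-0 too, from 13.1% to 30.2% (rMATS FDR 8e-06). Inclusion of an exon of RGLG1 (AT3G01650) rose from 19.6% ± 6.5 to 45.7% ± 1.6 (adjusted p = 3e-06), and use of an alternative 3' splice site of HKL1 (AT1G50460) from 17.8% ± 2.0 to 30.8% ± 1.4 (adjusted p = 6.6e-06), against 9.4% and 11.9% in Col-0 (rMATS FDR 1), a contrast that did not pass its own test (adjusted p = 0.99). The GPDHC1 event first named here and that of RGLG1 had no matched Col-0 event, so no TAIR10 position is given. Both genes changed in Col-0 too. Another intron of GPDHC1 was called in both accessions, from 66.6% to 83.4% in Col-0 and from 70.3% to 82.6% in Kn-0. An exon of RGLG1 with the same downstream spacing but a different upstream one went from 5.9% to 31.3% in Col-0 (adjusted p = 3.2e-09). An intron of ARFD1B (chromosome 1, 495683 to 495756) passed in Col-0, from 8.8% ± 4.0 to 40.8% ± 19.6 (adjusted p = 0.019), and went from 19.1% to 49.5% in Kn-0 without passing rMATS (FDR 0.13). Another of its introns (495490 to 495562) passed in Kn-0, from 47.5% ± 2.1 to 79.8% ± 6.7 (adjusted p = 0.012), and went from 55.3% to 69.4% in Col-0 (FDR 0.44). With the larger of the common and the event's own dispersion, chosen after the results were seen, the Col-0 intron did not pass (adjusted p = 0.25), and the Kn-0 intron did (adjusted p = 0.018). Neither response differed between the accessions (adjusted p = 1 for each). An exon of AT1G18390 went from 13.2% ± 1.2 to 40.1% ± 17.8 in Col-0 (adjusted p = 0.0098, or adjusted p = 0.1 with its own dispersion) and from 9.9% to 26.3% in Kn-0 (rMATS FDR 0.0032).

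Other events with large differences passed rMATS but not the refit. In Col-0 these were an intron of SAL2 (66.1% ± 3.1 and 96.0% ± 7.0, SD, n = 3, refit adjusted p = 0.45), an exon of AT1G78780 (refit adjusted p = 0.2) and splice sites of SDE5 (refit adjusted p = 0.37), AT2G26030 (refit adjusted p = 0.95) and AT1G17640 (refit adjusted p = 0.61). In Kn-0 they were an exon of AT1G78780 (refit adjusted p = 0.18) and splice sites of ABA4 (refit adjusted p = 0.15), AT1G72640 (refit adjusted p = 0.12), GC5 (refit adjusted p = 0.97) and the SR splicing factor SCL30 (refit adjusted p = 0.93). The refit called 40 events in Col-0, 29 of them higher under ABA, and 30 in Kn-0, 21 of them higher. With the larger of the common and the event's own dispersion it called 28 in Col-0, 17 of them higher, and 20 in Kn-0, 15 of them higher. These events are not independent observations, because those of 1 gene can share junction reads. In Col-0 the KAT5 exons and the 850-base KAT5 segment, with near-equal levels, are such a case. The split by direction depended on single libraries: without the third Col-0 ABA library 18 were higher and 13 lower, and in Kn-0 from 4 to 12 were lower without 1 library. The refit called 0 in both without moderation across events, and limma on log2 ratios called 0 in both, with 2589 and 2537 events at an unadjusted p under 0.05 against 2269 and 2306 in the refit.

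**Figure D2:**
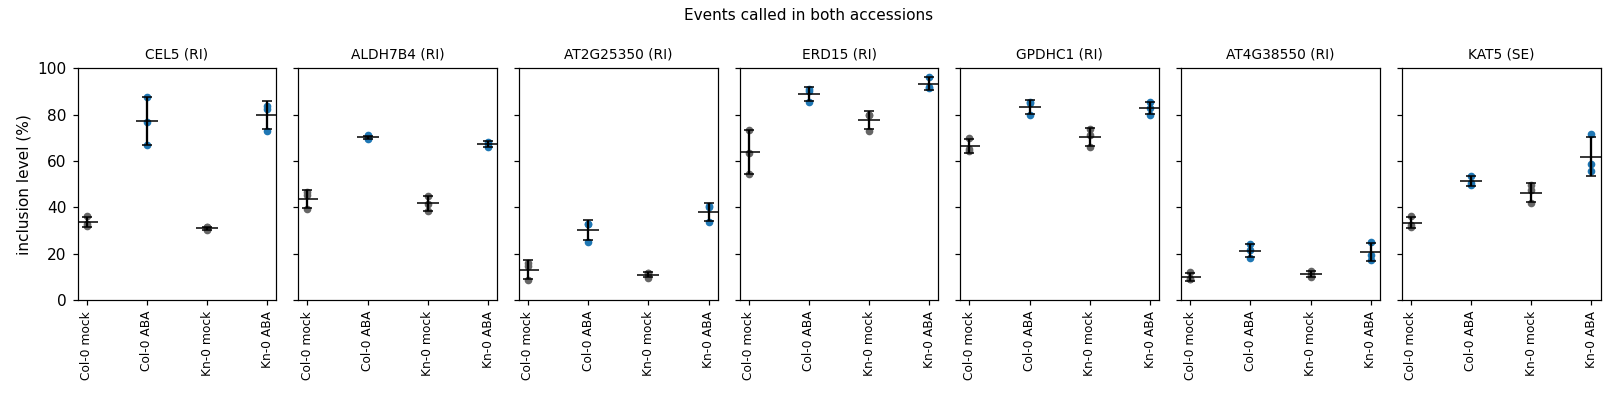
Inclusion level in percent (y axis) for each group (x axis) at 7 events called by rMATS in both accessions with at least 80 junction reads in every library, 1 per gene. Points are libraries and bars are the mean ± SD of 3 replicates, and the mean was higher under ABA in both accessions at each event plotted. The minimum of 80 reads was chosen after the values were seen, and it leaves out the shared events that fell.

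Matched by their splice junctions, a match chosen after the data were seen, 104 of the 222 called Col-0 events and 96 of the 161 called Kn-0 events were paired between the accessions. Of these paired calls, 63.5% of those in Col-0 and 59.4% of those in Kn-0 had the same sign in the other accession. In this match 14 pairs were called in both accessions against 0.11 expected (Fisher's exact p = 7.3e-26). The expectation was taken over all 89497 matched events, with those that had too few reads to be called, so it is too low. Pairs of the same gene, such as the ERD15 introns, are not independent either, so the p is too small. A pair counted as called in an accession where any event with its junctions was called, and the event with the most reads gave its levels. By these levels 12 of the 14 pairs moved in the same direction. An intron of ALDH7B4, an aldehyde dehydrogenase gene, went from 43.6% ± 4.0 (SD, n = 3) to 70.1% ± 0.8 in Col-0 and from 41.7% ± 3.2 to 67.2% ± 1.2 in Kn-0. An exon of KAT5 went from 33.4% ± 2.4 to 51.3% ± 2.1 in Col-0 and from 46.4% ± 4.0 to 61.9% ± 8.3 in Kn-0, where it did not pass the refit with its own dispersion (adjusted p = 0.33). Some events fell in both accessions, on fewer reads: an intron of AT4G03140 (95.5% to 72.1% in Col-0, 96.4% to 78.6% in Kn-0), one of ACO1 (98.2% to 79.9%, 98.5% to 82.5%) and an exon of AT1G78780 (93.0% to 57.7%, 91.0% to 64.4%). AT3G10820 and AT3G13580 moved in opposite directions, on as few as 20 and 10 junction reads in a library. The stricter match on all exon boundaries paired 55 of the called Col-0 events and 51 of the called Kn-0 events and gave 2 called in both. Of those paired calls, 56.4% in Col-0 and 54.9% in Kn-0 had the same sign in the other accession. The refit found 0 of 15601 matched events whose ABA response differed between the accessions, with 658 at an unadjusted p under 0.05, and limma on log2 ratios found 0, with 786. How large a difference between accessions this test could detect was not simulated.

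Splicing differed between the accessions in mock seedlings at 292 of 15601 matched events, in 194 genes, 177 of them with higher inclusion in Kn-0. Retained introns made up 112 of these, 91 higher in Kn-0 and 21 lower. Inclusion at an alternative 3' splice site of AT5G53010 (chromosome 5, 21490787 to 21490853) was 96.5% ± 0.5 (SD, n = 3) in Col-0 mock and 2.1% ± 2.1 in Kn-0 mock (adjusted p = 1.2e-13). An intron of REV1, a DNA polymerase gene (chromosome 5, 18056574 to 18056667), was retained at 93.9% ± 3.0 and 3.0% ± 3.6 (adjusted p = 3.2e-15). At a 5' splice site of AT5G10800 the levels were 92.8% ± 12.5 and 7.8% ± 5.4 (adjusted p = 4.5e-08), and at one in the 3' UTR of AT1G05870 they were 86.0% ± 1.7 and 6.2% ± 1.4 (adjusted p = 2e-128). An intron of AT1G31500 was retained at 1.5% ± 0.5 in Col-0 and 78.8% ± 5.0 in Kn-0 (adjusted p = 3.1e-45). The lowest number of junction reads in a library was 20 for AT5G53010, 17 for REV1, 14 for AT5G10800, 302 for AT1G05870 and 39 for AT1G31500. The count was 189 with limma on log2 ratios, 243 with the larger of the common and the event's own dispersion, and 987 of 25645 events matched by junctions. The Kn-0 events carry coordinates of an unstated assembly, so accession and annotation cannot be separated in this comparison.

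Genes with a called splicing event did not pass the expression test significantly more often than other genes. In Col-0, 43.1% of 174 such genes and 41.1% of the others passed (odds ratio 1.09, Fisher's exact p = 0.59), and in Kn-0, 56.0% of 134 and 50.7% of the others (odds ratio 1.24, Fisher's exact p = 0.23). With a log2 change of at least 1 the odds ratios were 2.42 (Fisher's exact p = 0.00057) and 2.51 (Fisher's exact p = 0.0028).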

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

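The one-library test of the lowered genes, the tests on genes listed at 0 and the regrouping tests were written after the results were seen. The division by the slope was added after the data were seen too, although its bounds were set before its outcome was known. The one-library test of the raised genes was written before its result.

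A test of the difference between accessions picked out 16 named genes. The change was more negative in Kn-0, in log2 units, for AT4G17580 (-5.88), AT5G05220 (-3.5), GASA3 (-3.12), CYP76C2 (-3.1), ATHSP22.0 (-3.07), BPS3 (-3.01), AT4G10500 (-2.98) and OCT1 (-2.92). It was more positive in Kn-0 for AT1G26420 (5.1), AT2G13900 (5.01), NAC042 (4.49), CYP81F2 (4.15), AT5G59680 (3.59), UMAMIT36 (3.43), PER4 (3.16) and AT3G28580 (3.1).

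Of the genes with a difference, 283 were raised by ABA in Col-0 and raised less, not raised or lowered in Kn-0. This set and the set of lowered genes below together hold 41 genes that passed in opposite directions in the accessions. A smaller amplitude does not apply to those. A smaller amplitude of the whole Kn-0 response was tested by division by the slope of 0.907. After it 57.6% of the members stayed past the threshold, so that slope alone does not account for them. But the slope was fitted over genes whose response did not differ, which favours a value near 1. A smaller slope was not tested, so a smaller amplitude is not excluded. Over the 133 members with junction reads, the share with the same direction was lowest, at 97.7%, without the second Col-0 mock library. Their median log2 difference was -0.54 with all libraries and from -0.5 to -0.57 without any 1. No 1 library therefore made the direction of these members as a set. But they were picked by their difference in these same libraries, so a high share was likely. Only the direction was asked, so single members enlarged by 1 library are not excluded. Separate normalization could at most add 1 offset to every fold change. Differing genes went both ways, 428 more positive and 330 more negative, which 1 offset cannot give. With each table centred on its median 759 genes differed. The median fold changes of all tested genes were -0.0005 in Col-0 and 0.0001 in Kn-0, so this centring tested little. A difference between the accessions in the response itself stays open, as does a smaller amplitude beyond that slope. The different annotation of the tables was not tested and stays open too.

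The 321 genes lowered by ABA in Col-0 and lowered less, not lowered or raised in Kn-0 were tested in the same way. After division by the slope 74.5% stayed past the threshold, and over 138 members with junction reads the lowest share with the same direction without any 1 library was 97.8%. Their median log2 difference was 0.59 with all libraries and from 0.55 to 0.65 without any 1. The direction of these 138 members as a set does not rest on 1 library, and the others could not be tested. As above, the members were picked in these same libraries and only the direction was asked, so the size of single differences was not tested. NAC042, CYP81F2 and PER4 rest in part on 1 library. Without the first Kn-0 ABA library their Kn-0 log2 ratios of junction reads were -1.51, -2.12 and -1.09. The biological difference named by the design stays open, as do the difference in annotation and, for the reason given above, a smaller amplitude beyond the slope.

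Some genes were listed at 0 in one table and had a mean above 100 normalized counts in the other, such as MYC2 (0 in Col-0, 3151.3 in Kn-0) and UBQ6 (13795 in Col-0, 0 in Kn-0). Of 217 such genes, 73.7% overlapped another annotated gene, against 30.9% of other genes, and the set was split by table only after this was seen. For the 158 listed at 0 in Col-0 the share was 91.8% (Fisher's exact p = 9.9e-58), in line with reads dropped as shared between overlapping genes. For the 59 listed at 0 in Kn-0 it was 25.4% (Fisher's exact p = 0.4), and the explanation cannot be told apart from others there, because only the Col-0 annotation was at hand. No biological explanation was tested.

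Regrouping the libraries bears on the refit of splicing. The real grouping gave 40 events in Col-0 and the highest of the other splits 3, with 1 of 10 splits as large, and in Kn-0 30 against 6, with 1 of 10. The mock comparison gave 292 against 0, with 1 of 10. With 10 splits the share cannot fall under 0.05. For the difference in ABA response, the real grouping gave 0 events and the highest of the others 37, and 100 of 100 splits were as large. A count of 0 fixed that outcome, so this test says nothing about chance. Splits that exchange the treatments within 1 accession turn a shared ABA response into a difference, but which splits gave the high counts was not examined.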

How the results depend on the processing

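The match on junctions, the division by the slope, the use of an event's own dispersion and the random lists matched on the Col-0 change were chosen after the results were seen. No paired analysis was possible because the values in a cell carry no replicate numbers. Libraries left out are named by their place in the cell, which was assumed to be constant across events and was not tied to a replicate number. Gene-level results could not be recomputed without single libraries.

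With a log2 change of at least 1, the genes changed were 2206 in Col-0 and 1755 in Kn-0, 242 differed between accessions, and the overlaps were 899 higher and 457 lower. At an adjusted p under 0.01, 490 genes differed, and after division by the slope 634. Correlations were 0.932 (Pearson) and 0.872 (Spearman) for genes with a mean of at least 50 counts, and Spearman rho was 0.897 for genes past the threshold in either table. The cause of these last shifts was not tested.

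For rMATS the counts in Col-0 and Kn-0 were 93 and 61 at an FDR under 0.01, 381 and 298 with no minimum difference, 103 and 67 with a difference of at least 0.2, 138 and 93 with a mean of 20 reads, and 541 and 440 with no minimum of reads, as looser or stricter filters would give. The refit gave 66 and 94 events with no minimum difference, and 0 and 0 both without moderation and with limma on log2 ratios, and the cause was not tested. Leaving out 1 library gave 30 to 32 events in Col-0 and 23 to 29 in Kn-0. The higher events in Col-0 went from 29 to 18 without the third ABA library, and the lower ones from 11 to 7 without the first mock or first ABA library. The lower ones in Kn-0 went from 9 to 4 without the second mock, the first ABA or the third ABA library. With the larger of the common and the event's own dispersion, 28 and 20 events were called. The share of genes with higher intron retention turned from under to over 50% with a mean of 20 reads (50.6% in Col-0, 51.1% in Kn-0) and with calls from the refit (68.2% and 73.3%), and the cause was not tested. The odds ratio of expression and splicing changes was 2.42 and 2.51 with a log2 change of at least 1.

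The mock comparison gave 189 events with limma, 114 with a difference of at least 0.2, 987 of 25645 with the match on junctions, whose cause was not tested, and 235 to 295 without 1 library. The difference in ABA response gave 0 to 3 events without 1 library, 3 of them without the third Col-0 mock library, 1 each without the second Col-0 mock, the first or second Col-0 ABA, the first Kn-0 mock or the second Kn-0 ABA library, and 0 without any other. Of 1376 values of named genes, lists and events under alternatives, 1227 kept their direction and side of the threshold, 147 lost the threshold, 2 passed it and 0 reversed. For genes and lists most alternatives changed only a threshold and left the direction fixed, so the count of 0 reversed says little about them. At 100 or more reads the refit recovered 85.7% (Col-0) and 85.2% (Kn-0) of changes of 0.2 simulated with a constant dispersion, but 0% and 3.7% with a dispersion that rose with depth.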

Other observations

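The lists of iron deficiency genes and of indole glucosinolate and camalexin genes were made after these genes were seen among the largest changes, so their tests were chosen only after the result was seen and are not independent evidence. The tests of the other lists were chosen before the data were examined. Iron deficiency genes fell in 10 of 18 measured members and rose in 4 in Col-0 (adjusted p = 0.00092 for lower), and fell in 12 of 19 in Kn-0 with 0 higher (adjusted p = 0.00041 for lower). Adjusted over the list alone, 15 and 12 changed. The median difference of the list was -0.06, at percentile 0.1 of random lists matched on the Col-0 change, whose median was 0.28, and 5 of 18 members passed the test of the difference, or 4 after division by the slope. Unlike that median, FRO2, FIT1, IRT1 and F6'H1 fell less in Kn-0 than in Col-0. FRO2, the ferric reductase of the root, had a log2 fold change of -3.04 ± 0.126 (standard error) in Col-0 and -1.67 ± 0.202 in Kn-0 in the authors' deposited table of each accession. FIT1, a regulator of iron uptake, stood at -2.45 ± 0.15 and -1.55 ± 0.121 in the same authors' deposited tables. IRT1 differed by 1.15 ± 0.27 (adjusted p = 0.0011) and F6'H1 by 1.5 ± 0.35 (adjusted p = 0.0012). After division by the slope F6'H1 passed (adjusted p = 0.02) and IRT1 did not (adjusted p = 0.13). Indole glucosinolate and camalexin genes fell in 11 of 14 members and rose in 1 in Col-0 (adjusted p = 6.9e-06 for lower), and fell in 4 of 14 and rose in 2 in Kn-0 (adjusted p = 0.71 for lower). Adjusted over the list alone, 13 and 6 changed. The median difference was 0.41, at percentile 85.2 of random lists matched on the Col-0 change, and 6 of 13 members measured in both passed the test of the difference, or 4 after division by the slope. IGMT3 was at -4.01 ± 0.173 in Col-0 and -1.29 ± 0.33 in Kn-0 in the authors' deposited table of each accession. CYP81F2, a member of this list, had 74, 6 and 4 junction reads in the Kn-0 ABA libraries. Its standard error was 0.925 in Kn-0 against 0.478 in Col-0, and those of IGMT1 were 0.713 against 0.127. Those of CYP79B3 (0.08 against 0.083) and MYB34 (0.055 against 0.087) were not larger in Kn-0. CYP71A12, lowered in Col-0, was at 3.66 ± 1.507 in Kn-0 in the authors' deposited table, without an adjusted p. Fewer decreases in Kn-0 can thus come from a wider spread there and do not by themselves show a difference of the list.

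Growth, hormone and organ lists changed in part. Early auxin response genes rose in 4 of 18 members and fell in 2 in Col-0, and rose in 3 with 0 lower in Kn-0 (7 and 3 adjusted over the list alone). Cell cycle genes fell in 1 of 8 in Col-0 and 3 of 8 in Kn-0 (1 and 3 adjusted over the list alone), and jasmonate genes rose in 3 and fell in 4 of 12 in Col-0 and rose in 6 and fell in 4 of 13 in Kn-0 (8 and 10 adjusted over the list alone). Circadian clock genes rose in 6 of 16 members and fell in 1 in Col-0, and rose in 5 and fell in 1 in Kn-0 (8 and 6 adjusted over the list alone). Root hair genes rose in 2 of 9 and fell in 1 in Col-0, and rose in 3 and fell in 1 in Kn-0 (3 and 4 adjusted over the list alone). Stomatal lineage and guard cell genes fell in 5 of 10 members in Col-0, and fell in 4 and rose in 1 in Kn-0 (5 and 5 adjusted over the list alone). Seed storage and oil body genes rose in 4 of 12 members in each accession (4 and 4 adjusted over the list alone), and with a log2 change of at least 1 the 4 in Col-0 passed as a list (adjusted p = 0.015) and the 3 in Kn-0 did not (adjusted p = 0.11). With no minimum change, no list of this paragraph passed its test, the smallest adjusted p being that of stomatal genes falling in Col-0 (adjusted p = 0.09).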
